A study of Mus musculus with 5 samples.

How the data were processed

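RNA was immunoprecipitated from mouse spermatocytes, the meiotic germ cells of the testis, taken from wild-type animals 3 weeks old. Per the labels' protocols, nuclei were sonicated, complexes of RNA, DNA and protein were captured with an antibody, the DNA was digested and the RNA was extracted, fragmented, reverse transcribed and sequenced as DNA nanoballs. A total of 3 samples used a rabbit antibody against γH2AX and 2 used rabbit IgG, which measures what binds without a specific antibody. The samples were grouped by the treatment given in the labels. The labels do not say whether samples of a group came from separate animals or preparations, so every p-value measures only the spread between these samples, which may be technical. The titles number the IgG samples 1 and 2, while the names of their files carry 2 and 3. The titles were followed.

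Per the submitters' processing notes, STAR 2.7.6a and featureCounts 2.0.2 were used. The deposited counts per region are whole numbers in the layout of STAR gene counts, with an unstranded column, a column for each strand, and rows for unmapped, multimapping, unassigned and ambiguous reads. The alignment settings and the source of the reference sequence are not given in the sources used here. The deposited annotation has 7 regions on a single sequence of 13568 nt, the transcribed 45S unit of ribosomal RNA. The regions cover that sequence without a gap, so a read mapped uniquely to it could not be unassigned. The unstranded column held 0 unassigned reads over all 5 samples, which is no evidence that the captured RNA was specific to the unit. A read mapped uniquely outside the unit would be unassigned, so the 0 argues against a reference with further sequence. Where multimapping reads lay is not recorded in the tables. With the unit as the only reference they would lie within it. Whether reads from ribosomal pseudogenes or similar sequences elsewhere in the genome were set aside before counting is not given in the sources used here. Coordinates are those of the deposited annotation, counted from 1 at the 5' end of the unit. They are not genome coordinates, and no genome build applies. Reads that mapped to several places or overlapped more than 1 region were not counted for any region by the authors.

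The deposited counts per bin cover the same unit in 1359 bins, 1353 of them 10 nt long. Per the file headers, featureCounts 2.0.2 was run with the paired-end option and without the option that lets a read count for several bins. Without that option a read that overlaps several bins is in general not counted. The bins held between 0.185% and 0.648% as many counts as the regions of the same sample. Which reads passed cannot be settled from the headers, and the bin profile is therefore a selected part of the reads. Coordinates (unit: other) were taken from the authors' annotation as deposited.

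From these counts, shares, counts per 1000000 sequenced reads (CPM) and ratios were computed. The library total was the sum of all rows of the unstranded column, between 19155821 and 20442571 reads. The strand with more counts over all samples, column 4 of the table, was called sense. The labels do not state the strand of the libraries. The unstranded count equalled the sum of both strands in 35 of 35 cells.

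Regions and bins were tested with edgeR 4.0.16 (quasi-likelihood F test, limma 3.58.1, R 4.3.3) on the counts as deposited, γH2AX against IgG, all 5 samples, no covariate. The main fit used the library total and no further factor, since enrichment over IgG needs the whole library as denominator. A second fit used the sum of the 45S counts, which asks only about the make-up of the 45S reads. With 7 regions no dispersion trend was fitted. Bins were kept by filterByExpr (about 10 counts in at least 2 samples and 15 in total). P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Log2 fold changes use a prior count of 0.125, and their standard errors were derived from the F statistic. Shares and ratios per sample were compared by exact permutation tests over the 10 arrangements of 3 against 2 samples, two-sided, whose smallest possible p is 0.2. These tests therefore cannot pass 0.05. The exact tests of the 4 planned single values were not adjusted for each other. Shares carry 95% Wilson intervals, which, like the floor of 3 counts for a feature with no counts, cover counting error only, since the reads carry no molecular identifiers.

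The fits were tested on simulated counts with the real library totals. Over 100 draws of 7 regions with 3 changed 8-fold, edgeR recovered 97.3% of the changed regions and called 20 of 400 unchanged ones. With no region changed it called 9 of 700. The simulated change was larger than any fitted fold of the unstranded region counts, the highest being 7.26 for the 5' ETS. Regions were drawn independently, whereas the regions of a real library can shift together. These draws therefore do not show the power for smaller changes, such as 2.75-fold in ITS1, or the false calls under a shared shift. For bins, counts were drawn a single time per dispersion, from rates averaged over all 5 samples. The simulated IgG libraries therefore held more binned counts than the real ones. At the dispersion of the data, edgeR recovered 6.06% of the tested bins changed 4-fold and 28.6% of those changed 16-fold, and called 0 of 214 unchanged bins. DESeq2 1.42.0 recovered 77.1% at 16-fold and called 7 of 214 unchanged bins.

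Before the data were examined, the comparisons, the tests and the rule for named items were fixed. Each region is named. Of the bins past the threshold under either library total, with all γH2AX values on one side of all IgG values, the 5 largest changes in each direction are named, leaving out bins within 200 nt of a named one. The most counted bin of each region is named as well. The 2 lists fixed in advance were the spacers and the mature regions. Lists of testicular cell type markers were set aside, because only the 45S unit was measured in the tables. The alternatives were another test (DESeq2, limma), TMM or median-of-ratios factors, other denominators, each strand alone, other filters, windows of about 100 nt, every 20th bin, a block for the replicate number and leaving out each sample. Replicates were compared before use: the chi-square over 7 regions was at least 22610 on 6 degrees of freedom for every pair within a group, so no library was a copy of another.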

Results

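The study asked which RNA is associated with γH2AX in mouse spermatocytes. γH2AX is the phosphorylated form of the histone variant H2AX. It marks chromatin around DNA double-strand breaks and, in meiotic prophase of males, the chromatin of the sex chromosomes. The counts cover the 45S unit of ribosomal RNA. RNA polymerase I transcribes it in the nucleolus as a precursor that is cut into 18S, 5.8S and 28S rRNA. The deposited annotation places the 5' external transcribed spacer (5' ETS) at positions 1 to 4175, 18S at 4176 to 6045, the internal spacer ITS1 at 6046 to 7044 and 5.8S at 7045 to 7201. The internal spacer ITS2 lies at 7202 to 8290, 28S at 8291 to 13003 and the 3' ETS at 13004 to 13568. Spacers belong to the precursor and its processing intermediates, whereas 18S, 5.8S and 28S are present both in precursors and in ribosomes. In each library spacers held between 1.10% and 3.46% of the counts assigned to a region. Most counts thus came from 18S, 5.8S and 28S.

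Sequencing depth was similar in all libraries. The IgG libraries held 19949854 and 19479393 reads, and the γH2AX libraries held 19155821, 20442571 and 20404442. Reads assigned to a single 45S region numbered 872019 and 1174548 with IgG and 5487596, 5755111 and 6278457 with γH2AX.

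Reads from the 45S unit made up a larger share of the sequenced reads with γH2AX than with IgG. Reads assigned to a 45S region were 5.20% ± 1.17 of all reads with IgG (SD, n = 2) and 29.2% ± 1.39 with γH2AX (SD, n = 3). The ratio of geometric means was 5.68, or 2.51 on the log2 scale with a replicate SD of 0.20. Each γH2AX library exceeded each IgG library, by 4.67 to 7.04 times. The counting error was small against this: the 95% Wilson interval was 4.36% to 4.38% for IgG replicate 1 and 28.6% to 28.7% for γH2AX replicate 1. The exact permutation test gave p = 0.2 (two-sided), the smallest p that 3 against 2 samples allow. All aligned reads, including multimapping reads and those across region borders, were 8.48% ± 2.07 with IgG and 63.7% ± 2.80 with γH2AX (SD, n = 2 and n = 3). The other reads, 91.5% with IgG and 36.3% with γH2AX, were unmapped, and what they were is not recorded. With the 45S unit as the only reference they would include any RNA from the rest of the mouse genome. The shares of sequenced reads need therefore not equal shares of the captured RNA. The ratio of the mean aligned shares was 7.52, above that of every single region, the highest being 7.26 for the 5' ETS. No fit used all aligned reads as the denominator, so a rise of a region is relative to all sequenced reads.

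Of the 7 regions, 5 rose with γH2AX relative to all sequenced reads, none fell, and ITS1 and the 3' ETS did not pass the test. All 3 mature rRNAs rose. 18S, the RNA of the small ribosomal subunit, went from 21749 ± 7892 CPM with IgG (SD, n = 2) to 147084 ± 15806 CPM with γH2AX (SD, n = 3). Its log2 fold change was 2.76 ± 0.46 (SE), with an adjusted p of 0.0042 in edgeR's quasi-likelihood test. 28S, the large RNA of the large subunit, went from 27482 ± 4193 to 132237 ± 8445 CPM, a log2 fold change of 2.27 ± 0.40 (edgeR, adjusted p = 0.0042). 5.8S, which pairs with 28S in the large subunit, was at 1800 ± 82.7 CPM with IgG. With γH2AX it reached 6974 ± 3822 CPM, 3.87 times higher, and its 3 libraries held 11104, 6255 and 3562 CPM (edgeR, adjusted p = 0.022). Without γH2AX replicate 1, the highest, 5.8S had a log2 fold change of 1.45 in place of 1.95 and no longer passed (edgeR, adjusted p = 0.075).

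Of the 4 spacers, 2 rose. The 5' ETS, the leading part of the precursor that is removed early in processing, went from 555 ± 311 CPM with IgG to 4031 ± 2830 CPM with γH2AX (SD, n = 2 and n = 3). Its log2 fold change was 2.86 ± 0.77 (SE; edgeR, adjusted p = 0.017). γH2AX replicate 2 held 7296 CPM of it, against 2292 and 2504 CPM in replicates 1 and 3. Without that replicate the log2 fold change was 2.11, still past the threshold (edgeR, adjusted p = 0.023). ITS2, which separates 5.8S from 28S, went from 281 ± 26.4 to 1249 ± 679 CPM, 4.44 times higher (edgeR, adjusted p = 0.017). ITS1, between 18S and 5.8S, was at 90.6 ± 56.8 CPM with IgG and 250 ± 76.7 CPM with γH2AX. Its log2 fold change of 1.46 ± 0.58 did not pass (edgeR, adjusted p = 0.052), although it did in DESeq2 (adjusted p = 0.019). The 3' ETS was at 45.4 ± 44.7 and 75.2 ± 15.98 CPM (edgeR, adjusted p = 0.36), the lowest level of any region. Adjusted over the list alone, 2 of the 4 spacers and 3 of the 3 mature regions passed, the same counts as over all regions.

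With 1 control left, 18S and 28S still passed, and the values of 5.8S and ITS2 stayed near the full ones although their calls were lost. Without IgG replicate 2 the 5' ETS, 5.8S and ITS2 had log2 fold changes of 2.38, 2.00 and 2.06 and did not pass (edgeR, adjusted p = 0.10 each), which left 2 regions in place of 5. Without IgG replicate 1, 5.8S and ITS2 had 1.91 and 2.25 and did not pass (edgeR, adjusted p = 0.080 and 0.054). The 5' ETS, at 3.59, still passed there, and ITS1 and the 3' ETS, at 2.31 and 2.445, passed as well (edgeR, adjusted p = 0.038, 0.027 and 0.016). The 5 calls rest on the library total as denominator: with TMM factors over the 7 regions, which shift their median log2 fold change by -2.09, no region passed (edgeR; 0 at an unadjusted p under 0.05, and 0 with DESeq2's own size factors), and the values for ITS1, 5.8S and the 3' ETS turned negative.

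**Figure D1:**
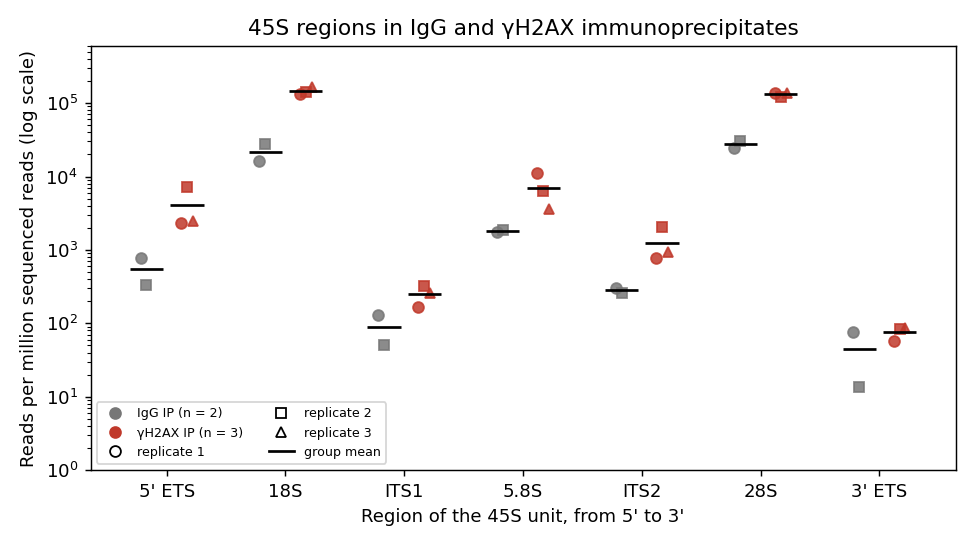
Reads as CPM of all sequenced reads (log axis) in each of the 7 regions of the 45S unit, from 5' to 3', for 2 IgG and 3 γH2AX libraries. Points are libraries, marker shapes are replicate numbers and bars are group means. In 6 regions each γH2AX library lies above both IgG libraries, and in the 3' ETS the groups overlap.

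The make-up of the 45S reads was compared with the sum of the 45S counts as the denominator. Mature rRNA dominated with both antibodies, and no region passed the test for a change in share. 18S held 41.2% ± 5.89 of the 45S counts with IgG and 50.3% ± 3.42 with γH2AX, and 28S held 53.3% ± 3.96 and 45.3% ± 2.58 (SD, n = 2 and n = 3). The 18S share was higher, and the 28S share lower, in each γH2AX library than in each IgG library, a separation that 2 of the 10 arrangements give by chance. 5.8S held 3.53% ± 0.64 with IgG and 2.42% ± 1.37 with γH2AX. For the 5' ETS the shares were 1.16% ± 0.86 and 1.40% ± 1.03. In edgeR's quasi-likelihood test 0 of 7 regions passed, 0 had an unadjusted p under 0.05, and DESeq2 also called 0 (1 at an unadjusted p under 0.05). The smallest edgeR adjusted p was 0.50, for ITS1 and the 3' ETS, whose log2 values were -1.16 ± 0.65 and -1.95 ± 0.88 (SE). The 5' ETS had 0.27 ± 0.83. Without IgG replicate 2 the 3' ETS passed as lower, at -2.78 (edgeR, adjusted p = 0.014).

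The spacer-to-mature ratio asks how much of the signal assigned to a single region comes from precursor-specific sequence. It leaves out reads that overlapped more than 1 region, which outnumbered the spacer counts in every library. They numbered 173922 and 297134 with IgG, against 25591 and 12888 spacer counts. With γH2AX they numbered 2385734, 2812350 and 3083558, against 63130, 198878 and 77316. Each border lies between a spacer and a mature region, so a read that runs across a border holds spacer sequence. Per assigned read, reads that overlapped more than 1 region were 0.226 with IgG and 0.472 with γH2AX (exact permutation test, two-sided, p = 0.2, the smallest possible). The ratio therefore does not cover all precursor-specific signal, and the part left out was larger with γH2AX. Spacers held 2.02% ± 1.30 of the 45S counts with IgG and 1.95% ± 1.31 with γH2AX (SD, n = 2 and n = 3). The ratio of spacer to mature counts was 0.946 times as high with γH2AX as with IgG. Single pairs of libraries ranged from 0.385 to 3.23 (exact permutation test, two-sided, p = 0.8). γH2AX replicate 2 had the highest spacer share, 3.46%, followed by IgG replicate 1 with 2.93%. The other 3 libraries lay between 1.10% and 1.23%. These unstranded counts add both strands, which differed between the groups. On the log2 scale the value was -0.08, against 0.37 on the sense strand and 1.89 with antisense counts subtracted, a setting chosen after the strand shares were seen (exact permutation test, two-sided, p = 0.2, the smallest possible).

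The strand of the reads separated the regions as well as the antibodies. Over all regions 93.0% ± 1.73 of the counts lay on the sense strand with IgG and 97.7% ± 0.64 with γH2AX (SD, n = 2 and n = 3). In 18S, 5.8S and 28S the sense share was above 90% in every library. In the 5' ETS it was 59.0% ± 5.99 with IgG and 85.2% ± 5.91 with γH2AX, and in ITS2 58.5% ± 8.15 and 89.3% ± 2.92. ITS1 stood at 53.5% ± 4.61 and 53.2% ± 6.76, and the 3' ETS at 61.0% ± 13.2 and 53.4% ± 2.38. Single libraries ranged from 47.0% to 60.4% in ITS1 and from 50.6% to 70.3% in the 3' ETS. In 5 regions, the 5' ETS, 18S, 5.8S, ITS2 and 28S, each γH2AX library had a higher sense share than each IgG library. The exact permutation p was 0.2 for each of these 5 (two-sided, the smallest possible), or 0.28 adjusted over the 7 regions.

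On the sense strand alone the 5' ETS was 11.1 times higher with γH2AX (log2 3.48 ± 0.84, SE; edgeR, adjusted p = 0.010) and ITS2 6.90 times higher (edgeR, adjusted p = 0.0098). Without γH2AX replicate 2 the folds were 6.17 and 4.61 (edgeR, adjusted p = 0.0084 and 0.0080). 18S was 7.04 times and 28S 5.02 times higher there (edgeR, adjusted p = 0.0050 for both). On the antisense strand no region passed edgeR's test (2 at an unadjusted p under 0.05), and the smallest adjusted p was 0.12.

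**Figure D2:**
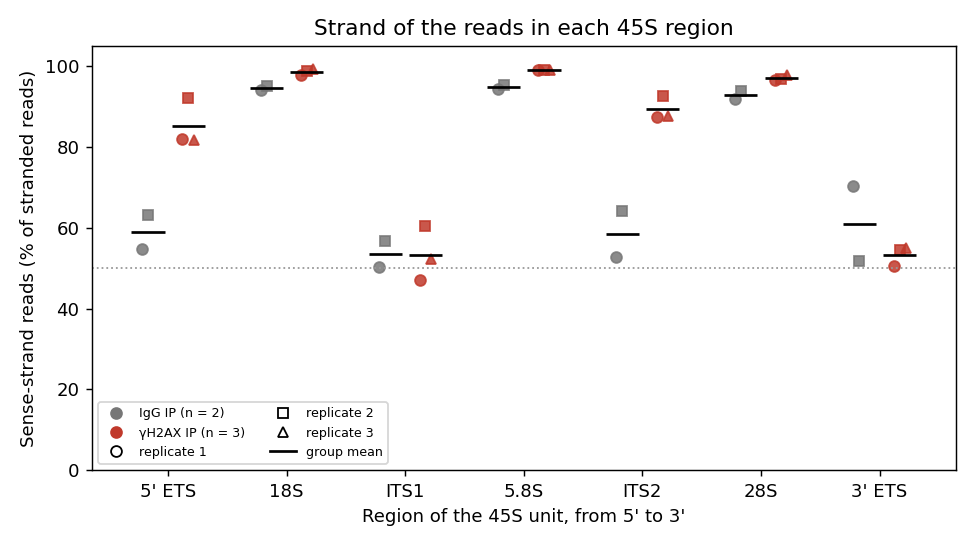
Sense-strand reads as a percentage of the stranded reads of each region, for 2 IgG and 3 γH2AX libraries. Points are libraries, marker shapes are replicate numbers, bars are group means and the dotted line marks 50%. The 5' ETS rises from a mean of 59.0% with IgG to 85.2% with γH2AX, while ITS1 has a mean of 53.5% and 53.2%.

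The binned table gives positions along the unit for a small selected part of the reads. It held 2211 and 2171 counts in the IgG libraries and 28767, 31392 and 40686 in the γH2AX libraries. Of 251 bins tested relative to all sequenced reads, 173 rose with γH2AX and 1 fell (edgeR's quasi-likelihood test, adjusted p under the threshold). Of the tested bins, 57 of 66 rose in 18S, 43 of 67 in the 5' ETS, 56 of 94 in 28S and 9 of 13 in ITS1. In 5.8S 4 of 4 rose, in ITS2 3 of 4 and in the 3' ETS 1 of 3. Neighbouring bins are not independent. A bin could pass the count filter on γH2AX counts alone, so the shares that rose may partly reflect this selection. They may also reflect the rate of binned counts per region count, which differed between the antibodies. It was 0.068% with IgG and 0.504% with γH2AX in 18S, and 0.196% and 0.269% in 28S. In ITS2, at 1.42% and 1.28%, and in the 3' ETS, at 49.3% and 11.7%, it was lower with γH2AX. Without the filter, 146 of 1093 bins rose and 7 fell in edgeR. Without IgG replicate 1, and likewise without IgG replicate 2, no bin passed in edgeR (137 and 144 at an unadjusted p under 0.05), although fitted log2 values such as that of the most counted 5' ETS bin (6.87 with all libraries) were 6.57 and 7.25. The bin that fell was not tested without γH2AX replicate 2 or 3, where it did not pass the count filter. Factors that centre the bins on each other removed most calls: TMM shifted the median log2 fold change of 4.91 by -3.32 and left 0 bins higher and 0 lower (edgeR, 67 at an unadjusted p under 0.05). DESeq2's own size factors shifted it by -3.66 and left 39 higher and 21 lower.

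The named bins with the largest rises had no count in either IgG library, and a ranking by fold favours such bins. Their folds compare the γH2AX mean with a floor of 3 counts over both IgG libraries and are lower bounds for that mean. The bounds leave out the spread between γH2AX libraries, and a single library can lie below them. The edgeR adjusted p of these bins lay between 0.018 and 0.028. The bin at 4706 to 4715 in 18S held 38.6 ± 24.8 CPM with γH2AX (SD, n = 3), at least 508-fold higher. In ITS1 the bin at 6906 to 6915 held 23.2 ± 1.92 CPM, at least 304-fold higher, and the 3 libraries had 407, 513 and 472 counts there. The bin at 3181 to 3190 in the 5' ETS was at least 173-fold higher, with 728 of its counts in γH2AX replicate 2 against 67 and 10 in replicates 1 and 3. In 18S the bins at 5416 to 5425 and 5716 to 5725 were at least 134-fold and 131-fold higher, the first with 584 of its counts in γH2AX replicate 3 against 6 and 33 in the others. Neither passed the count filter without γH2AX replicate 2 or 3, nor did the 5' ETS bin without replicate 1 or 2, so they were not tested there. The bin that fell lies in the 3' ETS at 13414 to 13423, with 10 and 94 counts in the IgG libraries and 0 in each γH2AX library, at least 53.3-fold lower (edgeR, adjusted p = 0.020). In the 3' ETS of IgG replicate 2 the bins held 93.3% as many counts as the region, against 5.27% in IgG replicate 1.

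Among the most counted bins, that of the 5' ETS, at 521 to 530, held 0.458 ± 0.151 CPM with IgG and 54.3 ± 13.9 CPM with γH2AX (edgeR, adjusted p = 0.018). That of 18S, at 4596 to 4605, held 0.505 ± 0.278 and 99.3 ± 71.0 CPM. The 28S bin at 10321 to 10330 held 0.307 ± 0.292 and 40.5 ± 6.24 CPM (edgeR, adjusted p = 0.018 for both). The 5.8S bin at 7065 to 7074 held 0.128 ± 0.181 and 8.53 ± 8.93 CPM (log2 5.99; edgeR, adjusted p = 0.036). Without γH2AX replicate 2 or 3 its log2 values were 4.77 and 6.15 and it did not pass (edgeR, adjusted p = 0.062 and 0.054). The ITS1 bin is the one at 6906 to 6915. The ITS2 bin at 7922 to 7931, with 385 of its counts in γH2AX replicate 2, did not pass the filter for the test relative to all sequenced reads. Relative to the sum of the binned counts it did not pass the test (edgeR, adjusted p = 0.61). The 3' ETS bin at 13284 to 13293 did not pass (edgeR, adjusted p = 0.080).

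Relative to the sum of the binned counts, 0 of 341 bins passed edgeR's test, 78 had an unadjusted p under 0.05, limma called 0, and DESeq2 called 36 higher and 43 lower. Without γH2AX replicate 1, edgeR called 3 higher and 9 lower. Within the 5' ETS, binned counts in the part nearer its 5' end outnumbered those in the equally long part nearer its 3' end by 2.49 ± 0.33 times with IgG and 1.66 ± 0.20 times with γH2AX (SD, n = 2 and n = 3; exact permutation test, two-sided, p = 0.2, the smallest possible). The direction depended on the division: a comparison of the 2 ends with the middle of the spacer left out gave 2.90 ± 0.45 with IgG and 3.16 ± 0.93 with γH2AX (SD, n = 2 and n = 3; exact permutation p = 1).

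**Figure D3:**
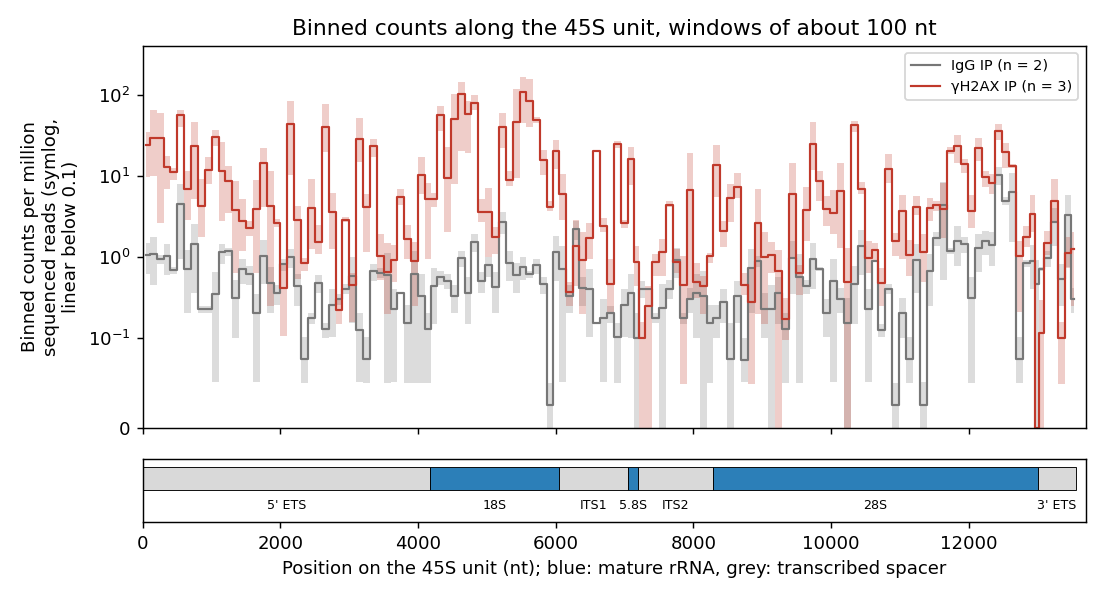
Binned counts as CPM of all sequenced reads in windows of about 100 nt along the 45S unit, on an axis that is logarithmic above 0.1 and linear below, with the 7 regions drawn to scale beneath. Lines are means of 2 IgG and 3 γH2AX libraries and shading spans the lowest to the highest library. The γH2AX line lies below the IgG line in 13 of 138 windows, 3 each in the 5' ETS, ITS2, 28S and the 3' ETS and 1 in ITS1.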

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

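Both results here lie in rows of the region tables that the comparisons of regions use only as part of the library total. They were chosen after the values were seen. Reads that the deposited tables count as multimapping were 20.8% ± 0.43 of all reads with γH2AX (SD, n = 3) and 2.08% ± 0.44 with IgG (SD, n = 2), a ratio of 9.99 (exact permutation test, two-sided, p = 0.2, the smallest possible). Reads that overlapped more than 1 region were 13.8% ± 1.33 of all reads with γH2AX and 1.199% ± 0.46 with IgG (exact permutation, p = 0.2), and 98.5% and 95.7% of them lay on the sense strand. Per assigned read, border-crossing reads were 2.08 times as frequent with γH2AX, 0.472 against 0.226, so that the counts per region leave out a larger part of the aligned reads in the γH2AX libraries. No group had 4 or more samples, so single libraries were not tested as outliers.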

How the results depend on the processing

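The 45S share of reads stayed higher with γH2AX under every alternative run. Its log2 ratio of 2.51 ranged from 2.27 to 2.74 when each library was left out, and was 2.81 without multimapping reads in the denominator, 0.89 on the antisense strand and 3.90 from the bins. The excess in sense share, 4.71 percentage points, ranged from 3.49 to 5.94 when each library was left out and was 25.3 over spacers only. The spacer-to-mature log2 ratio of -0.08 ranged from -0.80 to 0.64 when each library was left out, and its sign changed in 8 settings that moved it by less than the spread between libraries. With antisense counts subtracted, an alternative chosen after seeing the data, it was 1.89, and 1.23 without γH2AX replicate 2. The 5' ETS proximal-to-distal value of -0.59 ranged from -0.73 to -0.45 when each library was left out, but was 0.047 for the first 1000 nt against the rest and 0.088 with the middle of the spacer left out. The cause was not tested.

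The count of 5 higher regions ranged from 2 to 5 when each library was left out, the count of lower regions within the 45S total from 0 to 1, and the former was 0 with TMM, with DESeq2's own size factors and on the antisense strand. The first 2 of these centre the regions on each other, which removes a change shared by all. Relative to all sequenced reads, the 173 higher bins ranged from 0 to 141 and the 1 lower bin from 0 to 1 when each library was left out. Higher bins numbered 0 with TMM, 39 with DESeq2's size factors, 115 with a mean of at least 10 counts, 79 in windows and 11 for every 20th bin, where fewer features were tested. Lower bins numbered 0, 21, 7, 0 and 0 with TMM, DESeq2's size factors, no filter, windows and every 20th bin. Within the 45S total, where edgeR called 0 bins, leaving out a library gave 0 to 3 higher and 0 to 9 lower. There, DESeq2 called 36 higher and 43 lower, or 49 and 27 with its own size factors. Without a filter edgeR called 11 and 92, in windows 10 and 23, and for every 20th bin 1 lower.

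With a replicate block the higher regions numbered 0 (of 5), the higher bins 83 and the lower bins within the 45S total 1. The log2 values of the 5 regions were then 2.16 to 3.00 and their standard errors 1.01 to 1.12, against 1.95 to 2.86 and 0.40 to 0.77 without the block. 5.8S moved most, from 1.95 to 2.21. The libraries share only a number: deviations of same-numbered libraries over the 7 regions correlated at -0.498 and -0.366, and the deviations of the 2 IgG libraries mirror each other by construction. Paired by the numbers in the IgG file names, they correlated at 0.366 and -0.218, and no block was fitted for that pairing. The block leaves 1 degree of freedom and changed no other planned count by over 1.5 times.

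Single regions and bins whose log2 value changed sign were all short of the threshold in the setting that turned them. Relative to all sequenced reads, ITS1 was -0.53 with TMM and -0.49 with DESeq2's size factors, and the 3' ETS -1.22 and -1.18. The 3' ETS ranged from -0.034 (without IgG replicate 2) to 2.445 when each library was left out. 5.8S was -0.18 with TMM and -0.36 on the antisense strand, and the 3' ETS bin at 13284 was -0.74 and -1.10 with TMM and DESeq2's size factors. Within the 45S total, ITS2 was 0.057, 0.12 and 0.21 with TMM, DESeq2's size factors and the sense strand, 28S 0.25, 0.32 and, antisense, 0.14, and 5.8S 0.054 with DESeq2's size factors. Antisense counts gave -0.20 for 18S, 0.57 for ITS1 and 0.42 for the 3' ETS. When each library was left out, ITS1 ranged from -1.80 to 0.035, the 3' ETS from -2.78 to 0.17 and the 5' ETS from -0.53 to 1.34, with -0.34 without IgG replicate 2. The ITS2 bin at 7922 was -0.40 with limma-voom. Of the other alternatives, 108 values of main results moved by less than the spread between libraries or, for counts, by no more than 1.5 times. For single regions and bins, 319 values kept direction and side of the threshold, 58 kept direction but no longer passed, and 18 kept direction and newly passed. The sense strand without γH2AX replicate 2 was also added after seeing the data and kept 5 higher regions in number. With 1 IgG library left, that library is assumed to vary like the γH2AX libraries. The IgG libraries hold 2211 and 2171 binned counts, which limits the bins that can be tested. Spread between libraries limits them too: in simulated counts edgeR recovered 28.6% of the bins changed 16-fold at the dispersion of the data (0.817) and 97.2% at a dispersion of 0.204. The simulated IgG libraries held more binned counts than the real ones.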

Other observations

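The tests in this part, the subtraction of antisense counts included, were chosen after the strand shares had been seen. Counting sense minus antisense reads, the 5' ETS held 74.1 and 88.8 CPM in the IgG libraries and 1467, 6136 and 1585 CPM with γH2AX. ITS2 held 16.3 and 74.8 CPM with IgG and 582, 1729 and 711 CPM with γH2AX. The excess of sense reads in ITS1 stayed small in every library, between -10.3 and 66.8 CPM, and that of the 3' ETS between 0.462 and 31.3 CPM. Of the spacers, the 5' ETS and ITS2 therefore carried nearly all of the strand-specific signal of the γH2AX libraries.

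Antisense reads were a large part of the ITS1 reads in every library, where the sense share lay between 47.0% and 60.4%. Imperfect strand marking of sense RNA is argued against as the whole cause, because antisense reads per sense read were at least 14.9 times as frequent in ITS1 as in 18S of the same library. A background that covers both strands evenly, such as residual DNA, remains a candidate explanation. Among the 5' ETS, ITS1 and ITS2, antisense reads per kb differed by at most 1.17 times in each γH2AX library, but by 2.00 and 3.95 times in the IgG libraries. With the 3' ETS included they differed by up to 2.06 times with γH2AX and by up to 7.3 times with IgG. Antisense RNA adds reads to the antisense strand only, but together with sense RNA it could give a similar strand share. Without a library made with no reverse transcriptase it cannot be told apart from residual DNA.

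If such a background is subtracted strand for strand, the spacer-to-mature ratio no longer looks alike in both groups. Net sense spacer reads per 1000 net sense mature reads were 3.36 and 3.22 with IgG, and 7.62, 30.5 and 7.85 with γH2AX. Each γH2AX library exceeded each IgG library, by at least 2.27 times. Without γH2AX replicate 2 the ratio of geometric means was 2.35 in place of 3.71, so its size depends on that library, although the other libraries also lay above both IgG libraries. Chance stays open, since the exact permutation p of 0.2 is the smallest that 5 libraries can give, and edgeR on the sense strand alone called no change in make-up (smallest adjusted p = 0.47). The ratio also rests on the subtraction being valid, which was not tested, and leaves out the reads across region borders. A difference in what the 2 antibodies captured stays open as well, untested.

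The binned counts are not an even thinning of the reads counted per region. The 5' ETS took 28.1% of the binned counts of the γH2AX libraries but 1.40% of their region counts, and the rate at which reads reached a bin differed between regions by at least 68.8 times within each library. Levels in bins of different regions therefore cannot be set against each other. The rate differed between the antibodies as well: in 18S it was 0.068% with IgG and 0.504% with γH2AX. Bin folds and bin calls between the antibodies therefore also hold a difference in this rate.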
